A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

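Total RNA was extracted with Trizol and sequenced from 14 libraries, per the labels: EL4 tumours P0 and P3, EG7-OVA cells with DMSO, azacytidine or decitabine, and NKYS cells with DMSO or azacytidine, 2 libraries per group. The deposited EL4 and NKYS tables hold raw counts per gene, made by the authors with fastp, Trim Galore, STAR and featureCounts according to the submitters' processing notes. The deposited EG7 table holds counts per gene symbol. In it 145 values in 62 of 55969 entries were not whole. These were handled like expected counts as deposited by the authors, and how the authors made them is not stated and was not tested. The submitters' processing notes name the builds GRCh38 and mm10 for all samples alike, and the version and role of each tool are not given in the sources used here. There are 50559 gene entries for EL4 and 43432 for NKYS, the latter all mouse Ensembl genes, of which 42462 were matched to a mouse symbol and 40 were kept by their identifier. No raw reads were analysed here. Gene positions and classes came from GENCODE vM21 on mm10, matched by symbol.

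Values that were not whole were rounded for the count models. Genes were kept by filterByExpr and scaled by TMM in edgeR 4.0.16 under R 4.3.3. Each table was fitted on its own with 1 mean per group, the 6 EG7 libraries together, by glmQLFit. Groups were compared by the two-sided quasi-likelihood test, with Benjamini-Hochberg adjustment within a comparison and a threshold of adjusted p 0.05. Standard errors were the log2 fold change divided by the root of F, and intervals are 95%. A group with no read was set at a floor of 3 counts over the group for a bound on the fold, and groups with 1 to 3 reads were given a ratio with its exact counting interval.

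A read was found for 24601 to 28776 genes per EG7 library, 26898 to 28083 per EL4 library and 5037 to 5517 per NKYS library. Replicates correlated across genes at r = 0.958 to 0.991 in logCPM. The biological coefficient of variation was 0.188 in EL4, 0.244 in EG7 and 0.125 in NKYS. No libraries were pooled, no library was left out of the main comparisons, and every column of values was mapped to a sample.

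The 5 comparisons, their tests and 31 gene lists by theme were chosen before the data were examined. Lists of 5 or more tested genes were tested by camera in limma 3.58.1 on logCPM with a prior count of 2 and the preset correlation of 0.01, and also with the correlation estimated from the data. With an estimated correlation, camera uses only the few residual degrees of freedom left by groups of 2 libraries and has little power. A call lost in that setting therefore does not show that correlation between genes made the call. Fry was run beside them. It tests whether a list moves one way on balance and does not compare it with other genes. Genes of a list were also adjusted over the list alone. Lists were matched by mouse symbol in all tables, since the NKYS identifiers are mouse genes.

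Genes were named by a fixed rule in 3 parts. The first took up to 8 genes per direction with the largest fold among those past the threshold, with groups that did not overlap and a mean of 5 CPM or more in the higher group, leaving out predicted models and clones. The second took the 3 genes with the smallest p of each list called by camera and of 6 fixed lists (interferon, RNA sensing, class I, germline, checkpoint and cell cycle). The third was a fixed set: Dnmt1, Dnmt3a, Dnmt3b, Uhrf1, Cd274, Ifih1, Rigi (Ddx58), Isg15 and B2m, among others. The text names part of these genes, a few are not reported, and genes outside the rule are said to be chosen after their values were seen.

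The shared response to both drugs was set against 20 simulated draws in which 3 groups held no difference and both drugs were compared with the same controls. Overlaps between comparisons were tested by one-sided Fisher's exact test over the genes tested in both. Alternatives were median-ratio size factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (1 CPM in each library of a group and a total of 100), a replicate block, an absolute log2 fold change above 1, only the 4 libraries compared, and leaving out each library in turn. The replicate block pairs libraries by the number in the library name. The titles of the EG7 DMSO samples number them 2 and 3 where the library names say 1 and 2, and which holds is not known, so the pairing in EG7 is uncertain. Leaving out a library left an arm with 1 library, which was assumed to vary like the other groups. Alternatives on genes at 1 CPM in EG7 cells, on NKYS without 7SK and 7SL, and on DESeq2 without each P0 library were chosen after seeing the data.

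The pipeline was tested on simulated data with the spread of each table and 100 genes changed by a log2 fold of 1 and of 2. It recovered 33 and 72 in EL4, 32 and 59 with azacytidine, 38 and 53 with decitabine, 28 and 58 between the drugs, and 66 and 91 in NKYS. Unchanged genes made up 11.8%, 20.9%, 15.7%, 13.1% and 6.55% of calls, above the nominal 5%. A list shifted by 1 was called in 4 mouse-cell comparisons, with 0 others, but correlated lists were not tested. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.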

Results

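RNA sequencing was used to measure gene expression in 14 libraries that fall into 7 groups of 2. A pair of groups came from tumours of EL4, a mouse T-cell lymphoma line, labelled P0 and P3. The next 3 groups came from cultured EG7-OVA cells, a derivative of EL4 that expresses ovalbumin, given the solvent DMSO, azacytidine at 1.5 µM or decitabine at 0.2 µM. The last pair came from NKYS, a human NK/T-cell lymphoma line, given DMSO or azacytidine at 1.0 µM. Cells in culture were dosed at 0, 24 and 48 h and harvested at 72 h. Azacytidine and decitabine are analogues of cytidine and deoxycytidine that trap DNA methyltransferases, the enzymes that copy and place cytosine methylation.

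Total counts were 21926990 and 25328708 in the P0 libraries, and 21621580 and 22899073 in the P3 libraries. In EG7 they were 21048979 and 19116049 with DMSO, 15690747 and 16515050 with azacytidine, and 19414060 and 18341509 with decitabine. The NKYS libraries held 1571555 and 1842159 counts with DMSO and 1631696 and 1588971 with azacytidine. Below, values are log2 fold changes ± SE from edgeR with n = 2 libraries per group, and levels are mean CPM ± SD. The labels do not say whether replicates were separate cultures or animals, so the p-values measure the spread between these samples. Intervals of ratios and floors cover counting error only, and intervals of differences come from the fit.

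P3 tumours held less RNA from interferon-response, antigen-presentation and B-cell genes than P0 tumours. Camera lost these list calls with an estimated correlation (adjusted p = 0.596), a setting with little power at 2 libraries per group. Fry kept class I (0.0202) and B-cell genes (0.0248) but not interferon and class II genes (both 0.0518). The make-up of the libraries moved as well, with small RNA at 2.19% and 1.91% of counts in P0 against 0.96% and 1.26% in P3 and ribosomal RNA at 5.24% and 4.25% against 2.91% and 4.17%, and its bearing on the calls was not tested. Igtp, an immunity-related GTPase gene switched on by interferon, stood at 35.3 ± 3.18 CPM in P3 and 88.4 ± 1.65 CPM in P0 (-1.32 ± 0.10). Blk, a kinase of B cells, fell from 40.7 ± 1.8 to 0.331 ± 0.0953 CPM (-6.92 ± 0.22). Sgce, an imprinted sarcoglycan gene, rose from 2.21 ± 0.31 to 158 ± 6.53 CPM (6.15 ± 0.14). The comparison asks how the tumours labelled P3 differ from those labelled P0. The labels do not say what the numbers stand for, and the series title speaks of sensitising relapsed or refractory NK/T-cell lymphoma to PD-1 blockade with DNA methyltransferase inhibitors. Of 19993 genes tested, 7736 passed an adjusted p of 0.05, 3766 higher and 3970 lower in P3. The groups did not overlap for 76.1% of genes, where chance gives 33.3%. EdgeR calls were lost without P0 replicate 1 or 2, where the spread came from the P3 pair alone. That pair varied more (r = 0.963 between replicates, 0.991 in P0) and Igtp stayed at -1.35 and -1.31. The edgeR calls thus rest in part on the P0 pair's small spread. DESeq2 still called genes without P0 replicate 1 or 2. Of the 7736 genes, 4239 had an absolute log2 fold change above 1 (2073 higher and 2166 lower), and 4680 of the 12194 genes at 1 CPM or more in cultured EG7 cells passed.

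Among the largest rises in P3, Ppp1r9a, a neurabin that binds actin and lies near Sgce on chromosome 6, rose from 3.07 ± 0.345 to 586 ± 137 CPM (7.58 ± 0.25). Grik3, a kainate receptor, rose by 6.28 ± 0.33, and Vmn2r96, a vomeronasal receptor gene, by 5.96 ± 0.25. Erich2 and the ATPase gene Atp13a4 had no read in P0 and were at least 279-fold and 204-fold higher in P3. The transcription factor gene Sp9 held 260 reads in P3 and 3 in P0, a ratio of 88.3 (counting interval 29.9 to 431). Among the falls, Igll1, the surrogate light chain of the pre-B-cell receptor, and Rag1, the recombinase of antigen receptor genes, had no read in P3. They were at least 594-fold and 187-fold lower there. Ecrg4, a growth suppressor (-8.83 ± 0.24), the plakophilin gene Pkp1 (-8.66 ± 0.20) and Fcmr, the Fc receptor for IgM (-8.07 ± 0.88), fell. Cd8b1, a chain of the CD8 co-receptor, held 1 read in P3 against 384 in P0, a ratio of 377 (67.2 to 14900). Col22a1, a collagen of tissue junctions, held 3 reads against 2107, a ratio of 689 (236 to 3350). Each of these genes kept its direction without a P0 library but lost its call.

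Interferon-stimulated genes were lower in P3 as a group. Irgm1, a further GTPase gene (-1.57 ± 0.12), Igtp and the RNA exonuclease gene Isg20 (-1.55 ± 0.13) had the smallest p of the list. Isg15, a ubiquitin-like modifier, fell from 5.4 ± 1.88 to 0.991 ± 0.213 CPM (-2.44 ± 0.38). Of 40 genes tested, 27 were lower, 1 was higher (Sp110, chosen after its values were seen) and 12 did not pass. Adjusted over the list alone, 28 were lower and 1 higher. The list had a median log2 fold change of -0.83 and passed camera (adjusted p = 1.49e-06), with adjusted p = 0.596 with an estimated correlation and 0.0518 in fry. The named genes lost their calls without either P0 library. Markers of macrophages, which also express interferon-stimulated genes, summed to 489 and 469 CPM in the P3 libraries and 1550 and 1910 CPM in the P0 libraries.

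Genes that sense double-stranded RNA were split. Zbp1, a sensor of Z-form nucleic acid, fell by 2.29 on the log2 scale (SE 0.16) and Oasl2, of the oligoadenylate synthetase family, by 1.13 (SE 0.12). Ddx58, which encodes the RNA sensor RIG-I, was at 0.03 ± 0.12 (adjusted p = 0.874) and Ifih1, which encodes the sensor MDA5, at -0.52 ± 0.20 (adjusted p = 0.0915). Of 23 genes, 4 were higher, 7 lower and 12 did not pass, the same counts adjusted over the list alone. The median was -0.31 and camera gave adjusted p = 0.0581 (adjusted p = 0.657 with an estimated correlation), and 0.011 without P0 replicate 1. Zbp1 and Oasl2 lost their calls without either P0 library. Ifih1 passed without P3 replicate 1 (0.000862).

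Antigen-presentation genes were lower in P3. The class II genes H2-DMb1 (-3.30 ± 0.23) and H2-DMb2 (-4.69 ± 0.41), which help load peptide, and H2-Ob (-5.78 ± 0.59), which restrains this, fell with 9 of 10 list members, 0 rose and 1 did not pass. The count adjusted over the list alone was 9 lower, the median -3.39 and camera adjusted p = 0.000197 (adjusted p = 0.596 with an estimated correlation, and 0.0518 in fry). In class I presentation the immunoproteasome genes Psmb10 (-1.26 ± 0.12) and Psme1 (-0.95 ± 0.09) fell. Psme2 (-0.84 ± 0.09) is uncertain, since reads can be shared with its near-identical copy Psme2b. B2m, the light chain of class I molecules, was at 0.15 ± 0.15 (adjusted p = 0.447). Of 23 class I genes, 12 were lower, 1 higher and 10 did not pass, with 14 lower and 1 higher adjusted over the list alone. The class I median was -0.40 and camera adjusted p = 0.000207 (adjusted p = 0.596 with an estimated correlation). The called genes lost their calls without either P0 library. B2m passed without P3 replicate 1 (adjusted p = 0.0245). B-cell and dendritic markers, which include cells rich in class II molecules, fell in the same libraries.

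Checkpoint and co-stimulation genes moved both ways. Cd27, a co-stimulatory receptor of T cells, fell by 2.99 on the log2 scale (SE 0.11), Entpd1, the ectonucleotidase CD39, by 1.86 (SE 0.12) and Cd274, which encodes PD-L1, by 0.59 (SE 0.12), from 31.6 ± 1.84 to 21.0 ± 0.333 CPM. Cd40lg, the CD40 ligand of activated helper T cells, rose from 1.15 ± 0.287 to 16.6 ± 4.45 CPM (3.83 ± 0.31). Of 27 genes, 5 were higher, 15 lower and 7 did not pass, with 5 higher and 18 lower adjusted over the list alone. The median was -0.86 and camera adjusted p = 0.0107 (adjusted p = 0.596 with an estimated correlation). Chemokine and cytokine genes were lower: lymphotoxin beta Ltb (-2.23 ± 0.17) and the chemokines Cxcl16 (-2.39 ± 0.26) and Cxcl9 (-4.19 ± 0.51) fell. Of 17 tested, 1 was higher, 9 lower and 7 did not pass, with 1 higher and 11 lower adjusted over the list alone, a median of -2.01 and camera adjusted p = 0.000272 (adjusted p = 0.596 with an estimated correlation). The genes named here lost their calls without either P0 library. Macrophage and dendritic markers fell in the same libraries.

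Cell-cycle genes were slightly lower in P3. Mcm6 (-0.87 ± 0.10) and Mcm3 (-0.80 ± 0.11), subunits of the replication helicase, and the transcription factor gene E2f2 (-0.71 ± 0.10) fell. Of 35 genes, 22 were lower, 1 higher and 12 did not pass, with 26 lower and 2 higher adjusted over the list alone. The median was -0.45 and camera adjusted p = 0.000197 (adjusted p = 0.611 with an estimated correlation, and 0.0518 in fry). Samhd1, the dNTPase that also inactivates nucleoside drugs, fell from 166 ± 39.3 to 12.0 ± 2.18 CPM (-3.79 ± 0.22). Dut, the dUTPase (-0.91 ± 0.11), and Uck2, the kinase that activates azacytidine (-0.76 ± 0.16), fell as well. Of 16 nucleoside-metabolism genes, 9 were lower, 0 higher and 7 did not pass, with 9 lower adjusted over the list alone, a median of -0.43 and camera adjusted p = 0.00755 (adjusted p = 0.596 with an estimated correlation, and 0.0586 in fry). Among DNA methylation genes, Uhrf1, which guides DNMT1 to replicated DNA, fell by 0.79 on the log2 scale (SE 0.12). The methyltransferase genes Dnmt1 (0.03 ± 0.12), Dnmt3a (-0.25 ± 0.14) and Dnmt3b (-0.38 ± 0.16) did not pass, and Dnmt3a passed without P3 replicate 2 (0.000387) and Dnmt3b without P3 replicate 1 (0.0298). That list gave 3 higher, 4 lower and 10 not passed of 17, the same adjusted over the list alone, with a median of -0.13 and camera adjusted p = 0.48. All called genes named here lost their calls without either P0 library. Macrophage, dendritic and B-cell markers fell in the same libraries, macrophage sums to 489 and 469 CPM in P3 from 1550 and 1910 CPM in P0, and Samhd1 is abundant in myeloid cells.

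Markers of other cell types differed, though 8 of 12 B-cell genes passed the filter in EG7 cells. C1qc, a complement component made by macrophages (-1.94 ± 0.10), the Fc receptor gene Fcgr3 (-2.61 ± 0.17) and the lysozyme gene Lyz2 (-2.24 ± 0.17) fell with 17 of 20 macrophage markers, while 2 rose and 1 did not pass, the same adjusted over the list alone. Blk and Cd22, a B-cell lectin (-4.97 ± 0.40), fell with 9 of 9 B-cell markers, also 9 adjusted over the list alone. Ccr7 (-2.24 ± 0.14), Fscn1 (-2.16 ± 0.16) and Flt3 (-3.09 ± 0.27) fell with 9 of 12 dendritic markers, and 3 did not pass, the same adjusted over the list alone. Medians were -2.17, -5.43 and -2.24, with camera adjusted p = 2.37e-05, 4.13e-05 and 0.000877 (each adjusted p = 0.596 with an estimated correlation). Of neutrophil markers, Ngp (4.71 ± 0.79), a granule protein, and the calprotectin genes S100a8 (5.76 ± 1.06) and S100a9 (5.75 ± 1.06) rose. Of 11 neutrophil markers, 5 rose, 0 fell and 6 did not pass, with 5 adjusted over the list alone, a median of 2.32 and camera adjusted p = 0.0351 (adjusted p = 0.72 with an estimated correlation, and 0.305 in fry). That call was lost without P3 replicate 2 (0.11) or P0 replicate 1 (0.0969), and neutrophil sums were 44.5 and 159 CPM in P3 against 19.6 and 20.1 CPM in P0. All genes named here lost their calls without either P0 library, and in voom on all libraries S100a8 (0.0711) and S100a9 (0.0631) did not pass.

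Cytotoxic and regulatory T-cell genes and some matrix genes were lower in P3. Klrd1, a receptor of NK cells (-4.05 ± 0.33), and Gzma and Prf1, a granzyme and the pore-forming perforin (-2.24 ± 0.21 and -4.39 ± 0.58), fell. Foxp3, the master regulator of regulatory T cells (-1.74 ± 0.23), the orphan receptor gene Gpr83 (-2.87 ± 0.37) and Ikzf2 (-0.84 ± 0.10) fell too. Fbln1 (-1.56 ± 0.10) and Col6a1 (-1.63 ± 0.18), matrix genes, fell, while Pdgfrb, a growth factor receptor of mesenchymal cells, rose by 1.13 ± 0.12. The cytotoxic list gave 0 higher, 11 lower and 8 not passed of 19, with 12 lower adjusted over the list alone (median -1.97, camera adjusted p = 0.000675, and 0.596 with an estimated correlation). The regulatory T-cell list gave 0 higher, 6 lower and 3 not passed of 9, with 7 lower adjusted over the list alone (median -1.74, camera adjusted p = 0.0147, and 0.596 with an estimated correlation). The matrix list gave 1 higher, 9 lower and 9 not passed of 19, the same adjusted over the list alone (median -1.67, camera adjusted p = 0.00165, 0.657 with an estimated correlation and 0.154 in fry). These genes lost their calls without either P0 library.

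Other lists did not pass camera in the tumours. Among germline genes Xlr4a, whose reads can be shared with near-identical family members, rose by 1.31 ± 0.20 and Spo11, the meiotic recombination nuclease, by 1.00 ± 0.23. Tdrkh, a piRNA pathway gene, fell by 2.26 on the log2 scale (SE 0.48). Xlr4a, Spo11 and Tdrkh lost their calls without either P0 library. The germline list gave 6 higher, 1 lower and 5 not passed of 12, with 6 and 2 adjusted over the list alone (median 0.63, camera adjusted p = 0.226, and 0.0202 in fry). Imprinted genes gave 6 higher, 0 lower and 14 not passed of 20, with 6 adjusted over the list alone (median 0.33, camera adjusted p = 0.187, and 0.00918 without P3 replicate 2). T-cell identity genes gave 5 higher, 8 lower and 9 not passed of 22, the same adjusted over the list alone (median -0.26, camera adjusted p = 0.158, and 0.0243 in fry). Targets of p53 gave 4 higher, 10 lower and 16 not passed of 30, with 6 and 10 adjusted over the list alone (median -0.27, camera adjusted p = 0.226). NF-kB targets gave 4 higher, 7 lower and 6 not passed of 17, with 4 and 9 adjusted over the list alone (median -0.42, camera adjusted p = 0.0779, and 0.0383 without P0 replicate 1). Hypoxia genes gave 3 higher, 6 lower and 13 not passed of 22, with 3 and 8 adjusted over the list alone (median -0.28, camera adjusted p = 0.226, and 0.0403 without P3 replicate 2).

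Genes of the integrated stress response in the tumours gave 3 higher, 3 lower and 13 not passed of 19, with 2 and 3 adjusted over the list alone (median -0.11, camera adjusted p = 0.495). Genes that silence endogenous retroviruses gave 3 higher, 5 lower and 12 not passed of 20, the same adjusted over the list alone (median -0.046, camera adjusted p = 0.48). Retrovirus-derived genes gave 0 past the edgeR threshold of 5, and 0 adjusted over the list alone (median -0.44, camera adjusted p = 0.462). Genes known to be methylated in NK/T lymphoma gave 3 higher, 5 lower and 8 not passed of 16, the same adjusted over the list alone (median -0.46, camera adjusted p = 0.218). Endothelial markers gave 2 lower and 12 not passed of 14, with 1 lower adjusted over the list alone (median -0.26, camera adjusted p = 0.3, and 0.0256 without P3 replicate 1). Adipocyte markers gave 1 lower and 8 not passed of 9, with 0 adjusted over the list alone (median -1.86, camera adjusted p = 0.0846, 5.4e-05 without P3 replicate 1 and 0.0155 with the replicate block). Skeletal muscle markers gave 0 of 7 past the threshold (median 4.87, camera adjusted p = 0.493, and 0.000232 without P3 replicate 2), and their sum was 605 CPM in P3 replicate 1 and 1.27 CPM in P3 replicate 2. Keratinocyte markers (0 higher, 1 lower, 2 not passed of 3) and erythroid markers (1 higher, 2 lower, 1 not passed of 4) were too few for a test.

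**Figure D1:**
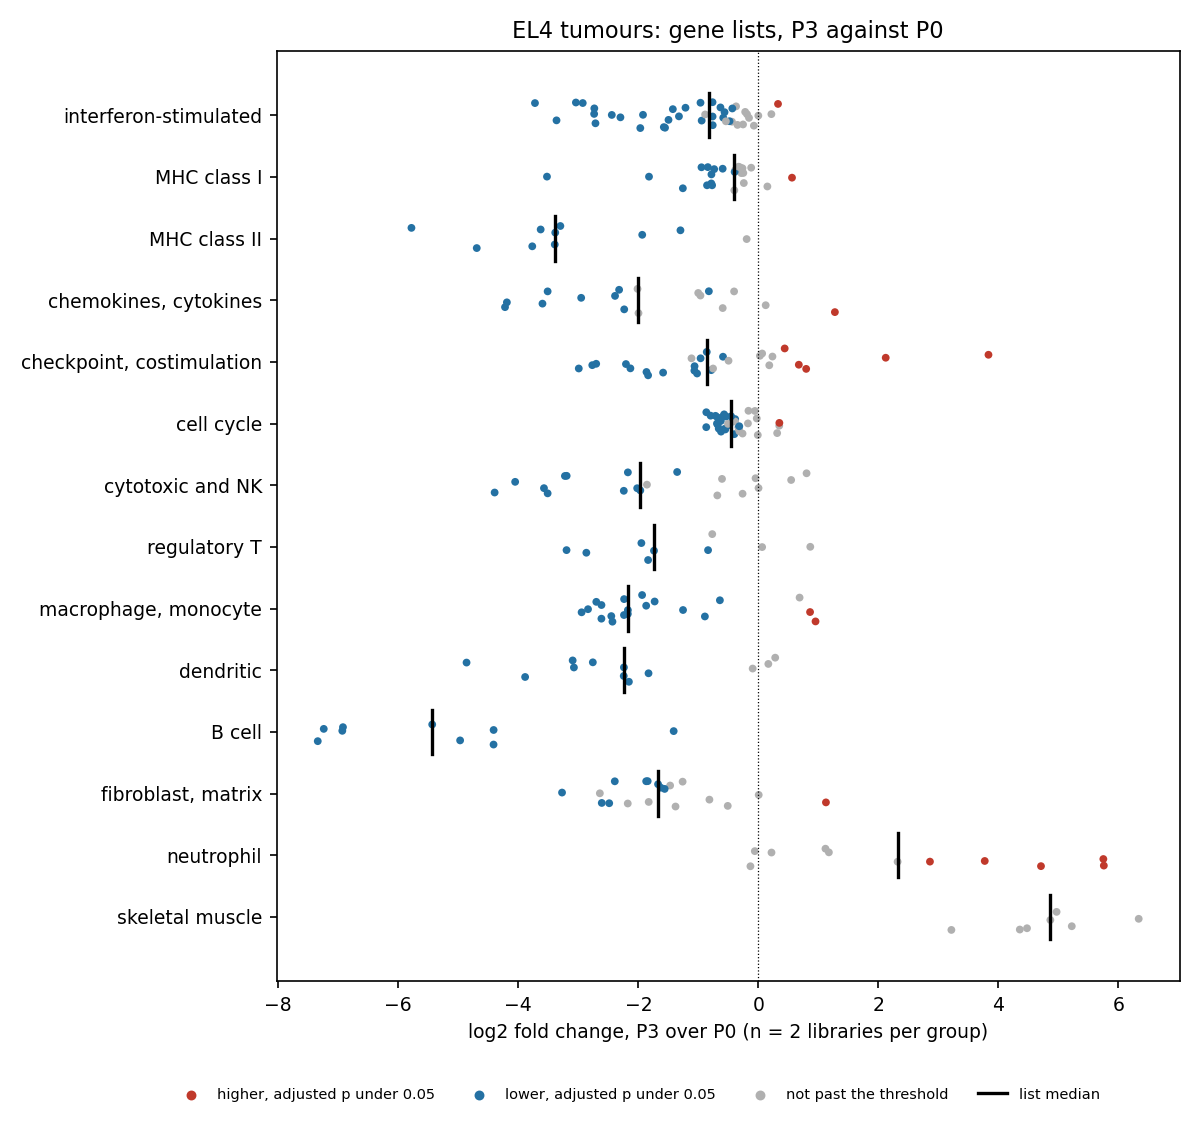
Log2 fold change of each tested gene of 14 fixed lists in P3 against P0 EL4 tumours, with red points higher, blue points lower and grey points not passed at an edgeR adjusted p of 0.05, and a black bar at each list's median. B-cell markers sit lowest with a median of -5.43.

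Azacytidine raised germline, interferon and RNA-sensing genes in EG7 cells and lowered cell-cycle genes. Camera lost these list calls with an estimated correlation (adjusted p = 0.319 to 0.406) and fry kept them (0.00613 to 0.0468). Xist, the RNA that coats the inactive X chromosome (X, 103460366 to 103483254, mm10), rose from 0.275 ± 0.0338 to 861 ± 328 CPM (11.58 ± 0.42). Plagl1, an imprinted zinc finger gene (chromosome 10, 13060504 to 13131694), rose from 0.425 ± 0.104 to 390 ± 124 CPM (9.82 ± 0.40). Igtp (chromosome 11, 58199556 to 58207591) rose from 10.1 ± 1.32 to 59.4 ± 1.43 CPM (2.56 ± 0.22). The comparison asks what the drug does to lymphoma cells in culture, which the series title ties to viral mimicry, an antiviral response to a cell's own transcripts. Of 19123 genes tested, 3881 passed, 2599 higher and 1282 lower, and 2613 of them had an absolute log2 fold change above 1. The groups did not overlap for 61.1% of genes, where chance gives 33.3%. Counts were 1675 without azacytidine replicate 1, 2226 without azacytidine replicate 2 and 2734 without DMSO replicate 1. The make-up of the libraries moved with the drugs. Ribosomal RNA took 1.49% and 1.8% of counts with azacytidine against 0.74% and 0.99% with DMSO, and small RNA 0.6% and 0.5% against 0.21% and 0.22%. Malat1 (1.43% and 2.22%) replaced Eef1a1 (0.88% in both) as the top gene, both chosen after their values were seen. Whether this bears on the calls below was not tested. The counting may not have used strand, so reads of Xist and its antisense gene Tsix cannot be told apart.

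The largest rises with azacytidine began from almost no expression. Magea13 and Magea9, cancer-testis genes that can share reads, and Peg10, an imprinted gene derived from a retrotransposon, had no read with DMSO. They were at least 559-fold, 458-fold and 482-fold higher with azacytidine. Atp13a5, an ATPase gene, and Rpl39l, a ribosomal protein gene of the testis with copies elsewhere in the genome, were at least 264-fold and 201-fold higher. Dcaf8l held 4652 reads against 1 with DMSO, a ratio of 5790 (1040 to 229000), and the cadherin gene Cdh19 4356 against 1, a ratio of 5420 (973 to 214000). Among the falls, Il7r, the interleukin-7 receptor, went from 97.4 ± 44.9 to 7.43 ± 2.16 CPM (-3.71 ± 0.52). Gcsam, a signalling adaptor of germinal centre cells, went from 53.2 ± 3.15 to 5.33 ± 0.0376 CPM (-3.32 ± 0.29). The adhesion molecule gene Sele fell by 3.88 on the log2 scale (SE 0.48) and H60c, a ligand of the NK-cell receptor NKG2D, by 3.42 (SE 0.60). Other genes of the naming rule lost their calls: Trat1, an adaptor of the T-cell receptor, with 2 reads with azacytidine against 234 with DMSO (DMSO over azacytidine ratio 93.9, 25.7 to 780), without azacytidine replicate 1 (0.0821) or 2 (0.122) or DMSO replicate 2 (0.263) and in voom (0.211), and Acox2 (-3.46 ± 0.67), Ccna2 (-1.16 ± 0.22) and Cdc25c (-1.12 ± 0.21) without azacytidine replicate 2 (0.0539, 0.0516) or, for Cdc25c, 1 (0.0526). The class II gene H2-Oa (1.30 ± 0.40) lost its call without azacytidine replicate 1 (0.162) or 2 (0.125) or DMSO replicate 1 (0.214), with the replicate block (0.0583) and in a fit of the 4 libraries alone (0.0764).

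Interferon and RNA-sensing genes rose with azacytidine. The GTPase gene Gbp2 rose from 0.900 ± 0.419 to 14.9 ± 0.439 CPM (4.04 ± 0.35) and the transcription factor gene Irf1 by 1.69 ± 0.19. Of 37 interferon-stimulated genes tested, 23 rose, 0 fell and 14 did not pass, with 29 higher adjusted over the list alone. The median was 1.13 and camera adjusted p = 1.62e-08 (adjusted p = 0.319 with an estimated correlation). Zbp1 rose by 3.15 ± 0.31, the oligoadenylate synthetase genes Oas3 and Oasl1 by 2.27 ± 0.25 and 3.43 ± 0.37, and Rigi, which encodes RIG-I, by 1.46 ± 0.19. Of 19 RNA-sensing genes, 13 rose, 0 fell and 6 did not pass, with 15 adjusted over the list alone. The median was 1.34 and camera adjusted p = 6.81e-06 (adjusted p = 0.319 with an estimated correlation). Ifih1 rose by 1.83 ± 0.57 and Isg15 by 1.65 ± 0.49, with adjusted p of 0.0476 and 0.0385. The call for Ifih1 was lost without azacytidine replicate 1 (0.296), azacytidine replicate 2 (0.0552) or DMSO replicate 1 (0.189). That for Isg15 was lost without azacytidine replicate 1 (0.227) or 2 (0.059) and without DMSO replicate 1 (0.0585) or 2 (0.122). Both were lost in voom (0.0731 and 0.0513) and with the replicate block (0.0671 and 0.0503).

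Antigen-presentation genes rose in part. H2-T23 and H2-T22, non-classical class I genes, rose by 1.90 ± 0.26 and 1.16 ± 0.17. H2-Q6 had no read with DMSO and was at least 45.3-fold higher, though members of the H2-Q family can share reads. B2m was at 0.40 ± 0.17 (edgeR adjusted p = 0.124; DESeq2 adjusted p = 0.048). Of 23 class I genes, 8 rose, 0 fell and 15 did not pass, with 9 adjusted over the list alone. The median was 0.49 and camera adjusted p = 0.00535 (adjusted p = 0.416 with an estimated correlation), a call lost without azacytidine replicate 1 (0.051) or DMSO replicate 2 (0.0573). Cd74, the invariant chain of class II molecules, rose from 4.38 ± 0.203 to 33.1 ± 11 CPM (2.92 ± 0.26). Of 7 class II genes, 2 rose, 0 fell and 5 did not pass, with 5 adjusted over the list alone, a median of 1.30 and camera adjusted p = 0.012 (adjusted p = 0.377 with an estimated correlation). Vsir, which encodes the checkpoint protein VISTA, rose by 2.33 ± 0.25 and Cd80, a ligand of CD28 and CTLA-4, by 2.06 ± 0.23. Lgals9, the lectin galectin-9, fell by 1.15 on the log2 scale (SE 0.18). Cd274 (chromosome 19, 29367455 to 29388095) rose from 6.76 ± 0.819 to 15.7 ± 4.4 CPM (1.22 ± 0.32, adjusted p = 0.0226), and lost its call without azacytidine replicate 2 (0.178) or DMSO replicate 2 (0.0756). Of 23 checkpoint genes, 6 rose, 3 fell and 14 did not pass, with 8 and 4 adjusted over the list alone, a median of 0.71 and camera adjusted p = 0.165 (0.0119 in fry).

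Most germline and some imprinted genes rose with azacytidine. Dazl, an RNA-binding protein of germ cells (chromosome 17, 50279395 to 50293636), rose from 0.126 ± 0.107 to 42.0 ± 0.67 CPM (8.31 ± 0.44), and the TFIID-related gene Taf9b by 2.59 ± 0.20. Tuba3b, a testis tubulin gene that can share reads with Tuba3a, held 2453 reads against 2, a ratio of 1530 (422 to 12600). Of 31 germline genes, 27 rose, 0 fell and 4 did not pass, with 29 higher and 2 lower adjusted over the list alone. The median was 7.20, or 3.88 with genes at 0 set to their bound, and camera adjusted p = 4.28e-14 (adjusted p = 0.377 with an estimated correlation). Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, rose from 0.150 ± 0.0699 to 42.6 ± 28.6 CPM (8.09 ± 0.65). Of 18 imprinted genes, 8 rose, 0 fell and 10 did not pass, with 8 adjusted over the list alone, a median of 0.93 and camera adjusted p = 3.77e-05 (adjusted p = 0.319 with an estimated correlation). Retrovirus-derived genes gave 2 higher and 3 not passed of 5, with 3 adjusted over the list alone, a median of 0.83 and camera adjusted p = 0.0614. It was 0.00746 without azacytidine replicate 2, 0.0499 without DMSO replicate 1 and 0.0107 in fry. Dnmt3a rose by 0.94 ± 0.19 (adjusted p = 0.00645, and 0.1 without azacytidine replicate 1), while Dnmt1 (-0.33 ± 0.16), Dnmt3b (0.05 ± 0.20) and Uhrf1 (-0.33 ± 0.20) did not pass. Of 18 DNA methylation genes, 1 rose, 0 fell and 17 did not pass, the same adjusted over the list alone, with a median of 0.11 and camera adjusted p = 0.686.

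Targets of p53 rose and cell-cycle genes fell. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose from 35.0 ± 5.09 to 368 ± 10.5 CPM (3.39 ± 0.25) and Btg2, an antiproliferative gene, from 92.2 ± 9.08 to 590 ± 63.4 CPM (2.68 ± 0.19). The kinase gene Plk2 held 716 reads against 1, a ratio of 892 (160 to 35300). Of 31 targets, 17 rose, 1 fell and 13 did not pass, with 21 and 1 adjusted over the list alone, a median of 0.83 and camera adjusted p = 2.4e-05 (adjusted p = 0.377 with an estimated correlation). Bub1, a mitotic checkpoint kinase, fell by 1.29 on the log2 scale (SE 0.23). Of 35 cell-cycle genes, 1 rose, 21 fell and 13 did not pass, with 1 and 26 adjusted over the list alone, a median of -0.70 and camera adjusted p = 1.76e-08 (adjusted p = 0.406 with an estimated correlation). Among NF-kB targets, Nfkbiz (1.75 ± 0.18) and Nfkbia (1.28 ± 0.21), inhibitors or modulators of NF-kB, and the adaptor gene Traf1 (3.42 ± 0.38) rose. Of 14, 7 rose, 0 fell and 7 did not pass, with 7 adjusted over the list alone, a median of 1.52 and camera adjusted p = 0.00376 (adjusted p = 0.377 with an estimated correlation).

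Some hypoxia, glycolysis and stress genes fell with azacytidine. Pdk1, which holds pyruvate back from mitochondria (-1.19 ± 0.16), the oxidoreductase gene Ero1a (-0.96 ± 0.16) and the glycolytic gene Pfkp (-0.94 ± 0.17) fell. Of 22 hypoxia and glycolysis genes, 0 rose, 6 fell and 16 did not pass, with 1 and 7 adjusted over the list alone, a median of -0.45 and camera adjusted p = 0.00133 (adjusted p = 0.377 with an estimated correlation). Psat1, of serine synthesis (-1.17 ± 0.17), the cystine transporter gene Slc7a11 (-1.15 ± 0.22) and the glutathione-degrading gene Chac1 (-2.20 ± 0.42) fell. Of 19 integrated stress genes, 3 rose, 6 fell and 10 did not pass, with 3 and 7 adjusted over the list alone, a median of -0.25 and camera adjusted p = 0.0247 (adjusted p = 0.416 with an estimated correlation). That call was lost without azacytidine replicate 2 (0.128), and fry gave 0.0663. Pdgfrb (3.83 ± 0.45) and the collagen gene Col1a1 (3.33 ± 0.50) rose, and Col1a2, with no read in DMSO, was at least 164-fold higher. Of 10 matrix genes, 4 rose, 1 fell and 5 did not pass, with 5 and 1 adjusted over the list alone, a median of 1.55 and camera adjusted p = 0.0332 (adjusted p = 0.377 with an estimated correlation).

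The remaining lists did not pass camera with azacytidine. Chemokines gave 3 higher and 12 not passed of 15, with 3 adjusted over the list alone (median 0.46, camera adjusted p = 0.244, and 0.0392 in fry). T-cell identity gave 6 higher, 2 lower and 14 not passed of 22, with 7 and 2 adjusted over the list alone (median 0.35, mean -0.077, camera pointing up with adjusted p = 0.287). The cytotoxic list gave 1 lower and 5 not passed of 6, with 2 higher and 2 lower adjusted over the list alone (median -0.48, mean 0.23, camera pointing down with adjusted p = 0.492). Regulatory T-cell genes gave 2 higher, 1 lower and 7 not passed of 10, with 4 and 1 adjusted over the list alone (median 0.54, camera adjusted p = 0.387, and 0.0149 in fry). Macrophage genes gave 5 higher and 8 not passed of 13, with 5 adjusted over the list alone (median 0.46, camera adjusted p = 0.106, and 0.02 without DMSO replicate 2). Genes methylated in NK/T lymphoma gave 5 higher, 2 lower and 8 not passed of 15, with 6 and 2 adjusted over the list alone (median 0.56, camera adjusted p = 0.323, and 0.0264 in fry). Genes that silence retroviruses gave 2 higher, 2 lower and 16 not passed of 20 (2 and 2 adjusted over the list alone, median -0.082, mean 0.034, camera pointing down with adjusted p = 0.613). Nucleoside genes gave 2 higher, 3 lower and 11 not passed of 16, with 2 and 4 adjusted over the list alone. The nucleoside median of 0.0089 and mean of 0.041 lay above 0 where camera pointed down (adjusted p = 0.44). B-cell genes gave 0 of 8 past the threshold, also adjusted over the list alone (median 0.037, camera adjusted p = 0.686). Endothelial genes gave 1 higher of 7, also adjusted over the list alone (median -0.11, mean 0.40, camera pointing up with adjusted p = 0.686). Too few for a test were neutrophil (3 higher of 3), dendritic (1 lower of 4), keratinocyte (1 higher and 1 lower of 4), skeletal muscle (0 of 3), adipocyte (0 of 2) and erythroid (0 of 1) genes.

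**Figure D2:**
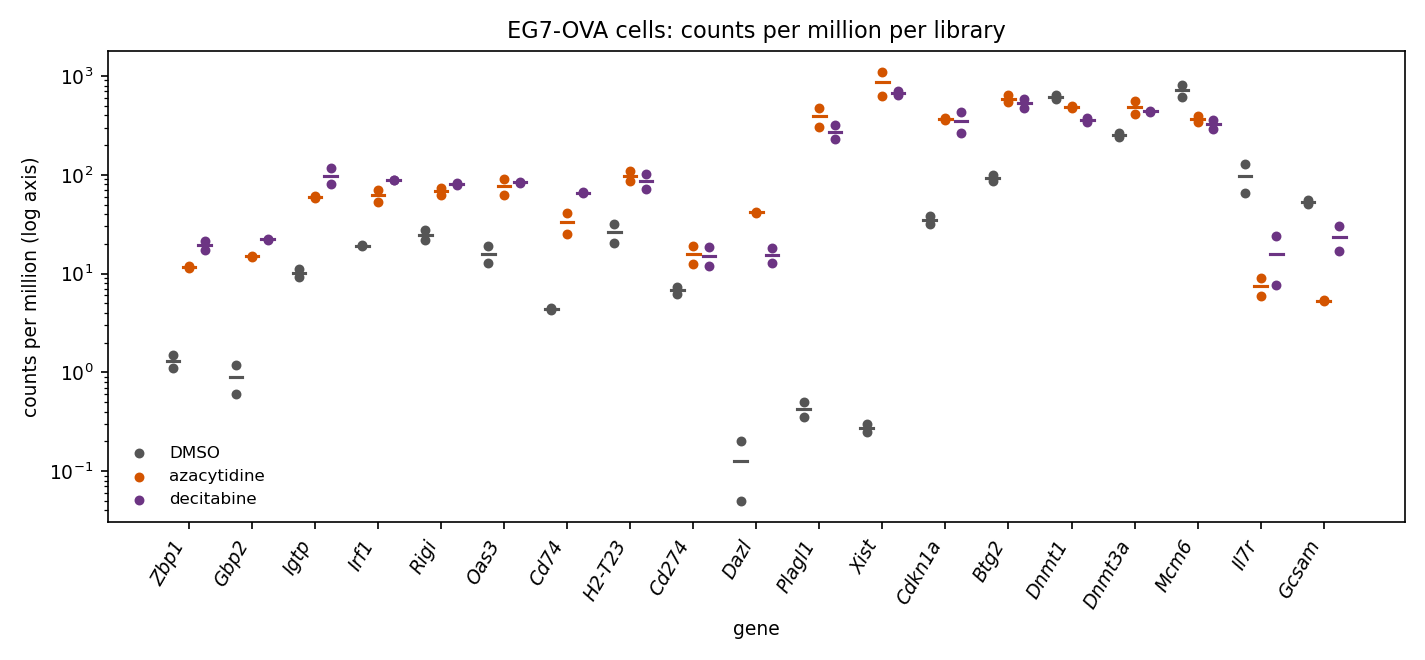
CPM of 19 genes in each EG7 library on a log axis, with DMSO, azacytidine and decitabine in separate colours and a bar at each group's mean. Xist averaged 0.275 CPM with DMSO, 861 CPM with azacytidine and 669 CPM with decitabine.

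Decitabine raised Xist, Plagl1 and Igtp as well. Xist rose to 669 ± 42.6 CPM (11.21 ± 0.42), Plagl1 to 273 ± 62.6 CPM (9.30 ± 0.39) and Igtp to 98.3 ± 25.0 CPM (3.28 ± 0.23), from the DMSO levels of 0.275, 0.425 and 10.1 CPM. The comparison asks what the deoxycytidine analogue does to the same cells. Of 19123 genes tested, 3198 passed, 2376 higher and 822 lower, and 2216 of them had an absolute log2 fold change above 1. The groups did not overlap for 58.8% of genes, where chance gives 33.3%. Counts were 1520 without decitabine replicate 2 and 2049 without DMSO replicate 1. Mitochondrial transcripts took 2.61% of counts in decitabine replicate 1 and 0.97% to 1.21% in the other EG7 libraries. Ribosomal RNA took 2.0% and 1.64% with decitabine and small RNA 0.31% and 0.46%, also above both DMSO libraries. Cdh19 held 5422 reads against 1, a ratio of 5710 (1030 to 226000), and Dcaf8l 3325 against 1, a ratio of 3500 (628 to 138000). With no read in DMSO, Magea9 and Magea13, which can share reads, were at least 362-fold and 329-fold higher, Col1a2 at least 241-fold, and Vmn2r96 and the leukocyte gene Lsp1 each at least 140-fold. Il7r fell to 15.9 ± 11.6 CPM (-2.61 ± 0.48) and Chac1 to 6.83 ± 1.23 CPM (-2.57 ± 0.43). Sox1ot, a transcript that overlaps Sox1, fell by 2.18 on the log2 scale (SE 0.27) and H2-Q2, whose reads may be split among the H2-Q family, by 2.40 (SE 0.27).

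Most interferon and RNA-sensing genes and some presentation genes rose with decitabine. Gbp2 rose to 22.2 ± 0.532 CPM (4.62 ± 0.36) and Irf1 by 2.21 ± 0.19. Isg15 was at 1.46 ± 0.49 (adjusted p = 0.0688). Of 37 interferon genes, 24 rose, 0 fell and 13 did not pass, with 30 adjusted over the list alone, a median of 1.12 and camera adjusted p = 3.11e-11 (adjusted p = 0.146 with an estimated correlation). Zbp1 rose by 3.90 ± 0.32, Oas3 by 2.41 ± 0.25 and Rigi by 1.72 ± 0.19, and Ifih1 by 2.10 ± 0.57 (adjusted p = 0.0319). The Ifih1 call was lost without decitabine replicate 1 (0.227) or DMSO replicate 1 (0.134). Of 19 RNA-sensing genes, 15 rose, 0 fell and 4 did not pass, with 15 adjusted over the list alone, a median of 1.49 and camera adjusted p = 4.3e-06 (adjusted p = 0.146 with an estimated correlation). Cd74 rose to 65.9 ± 0.399 CPM (3.91 ± 0.26) and the class II gene H2-Eb1 by 1.66 ± 0.23. Of 7 class II genes, 4 rose, 0 fell and 3 did not pass, with 6 adjusted over the list alone, a median of 1.68 and camera adjusted p = 0.000313 (adjusted p = 0.146 with an estimated correlation). H2-T22 rose by 1.23 ± 0.17 and H2-T23 by 1.72 ± 0.26, and B2m was at 0.48 ± 0.17 (edgeR adjusted p = 0.0767; DESeq2 adjusted p = 0.0187). Of 23 class I genes, 8 rose, 0 fell and 15 did not pass, with 12 adjusted over the list alone, a median of 0.48 and camera adjusted p = 0.0031 (adjusted p = 0.335 with an estimated correlation, and 0.0518 without DMSO replicate 2).

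Some checkpoint, chemokine, regulatory T-cell and NF-kB genes rose with decitabine, while most of each list did not pass and the list calls were lost with an estimated correlation (adjusted p = 0.146 to 0.274). Cd80 rose from 9.29 ± 1.65 to 60.2 ± 3.68 CPM (2.70 ± 0.23), Vsir by 2.46 ± 0.25 and Cd276, which encodes the checkpoint ligand B7-H3, by 3.68 ± 0.56. Cd274 rose to 15.1 ± 4.58 CPM (1.16 ± 0.32, adjusted p = 0.0323), a call lost without decitabine replicate 2 (0.268), DMSO replicate 1 (0.0633) or DMSO replicate 2 (0.1). Of 23 checkpoint genes, 9 rose, 2 fell and 12 did not pass, with 11 and 2 adjusted over the list alone, a median of 0.85 and camera adjusted p = 0.00198 (adjusted p = 0.146 with an estimated correlation). Il10, an immunosuppressive cytokine, held 69 reads against 3 (ratio 24.2, 7.95 to 120). Of 15 chemokine and cytokine genes, 5 rose, 0 fell and 10 did not pass, with 7 adjusted over the list alone, a median of 1.79 and camera adjusted p = 0.000791 (adjusted p = 0.146 with an estimated correlation). Lrrc32, which displays latent TGF-beta on regulatory T cells, rose from 0.251 ± 0.143 to 44.6 ± 26.2 CPM (7.44 ± 0.56). Of 10 regulatory T-cell genes, 3 rose, 0 fell and 7 did not pass, with 3 adjusted over the list alone, a median of 0.97 and camera adjusted p = 0.0475 (adjusted p = 0.274 with an estimated correlation). That call was lost without decitabine replicate 2 (0.073) or DMSO replicate 1 (0.0683), and with the replicate block (0.0508). Nfkbiz (1.98 ± 0.18), Traf1 (3.30 ± 0.38) and Nfkbie (1.51 ± 0.29) rose with 6 of 14 NF-kB targets, while 0 fell and 8 did not pass. That list had 7 adjusted over the list alone, a median of 1.21 and camera adjusted p = 0.0031 (adjusted p = 0.274 with an estimated correlation).

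Most germline and p53 genes and some imprinted genes rose with decitabine. Dazl rose to 15.4 ± 3.67 CPM (6.87 ± 0.44), Taf9b by 1.89 ± 0.20 and Cdkn1c to 10.9 ± 1.96 CPM (6.12 ± 0.64), and Peg10, with no read in DMSO, was at least 59.7-fold higher. Of 31 germline genes, 21 rose, 0 fell and 10 did not pass, with 27 adjusted over the list alone. The median was 5.58, or 2.59 with genes at 0 set to their bound, and camera adjusted p = 3.11e-11 (adjusted p = 0.274 with an estimated correlation). Of 18 imprinted genes, 7 rose, 0 fell and 11 did not pass, with 10 adjusted over the list alone, a median of 1.00 and camera adjusted p = 3.48e-05 (adjusted p = 0.146 with an estimated correlation). Retrovirus-derived genes gave 3 higher and 2 not passed of 5, with 3 adjusted over the list alone, a median of 1.08 and camera adjusted p = 0.0349 (adjusted p = 0.274 with an estimated correlation). That call was lost without decitabine replicate 2 (0.0868), DMSO replicate 1 (0.0683) or DMSO replicate 2 (0.13). Cdkn1a rose to 349 ± 115 CPM (3.31 ± 0.25) and Trp53inp1, a stress-induced p53 partner, by 2.34 ± 0.18. Of 31 p53 targets, 19 rose, 0 fell and 12 did not pass, with 21 adjusted over the list alone, a median of 0.92 and camera adjusted p = 8.87e-08 (adjusted p = 0.146 with an estimated correlation).

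Cell-cycle genes fell with decitabine, and Dnmt1 with them. Cdc25c, a phosphatase that starts mitosis, fell by 1.11 on the log2 scale (SE 0.21), Mcm6 by 1.14 (SE 0.20) and Mcm7 by 1.00 (SE 0.19). Mcm6 and Mcm7 lost their calls without decitabine replicate 2 (0.0542 and 0.0551). Of 35 genes, 0 rose, 27 fell and 8 did not pass, with 29 adjusted over the list alone, a median of -0.79 and camera adjusted p = 1.05e-11 (adjusted p = 0.274 with an estimated correlation). Dnmt1 went from 611 ± 36.6 to 358 ± 19.6 CPM (-0.77 ± 0.16, adjusted p = 0.00984), Uhrf1 by -0.80 ± 0.20 (0.0222) and Dnmt3a by 0.80 ± 0.19 (0.0162), while Dnmt3b was at -0.23 ± 0.20. Dnmt1 lost its call without decitabine replicate 1 (0.0682) or 2 (0.0642). Uhrf1 lost it without these (0.0786 and 0.126) or DMSO replicate 1 (0.109), and Dnmt3a likewise (0.0809, 0.0894 and 0.0728). Of 18 DNA methylation genes, 2 rose, 3 fell and 13 did not pass, with 3 and 3 adjusted over the list alone. The median of 0.14 and mean of 0.21 lay above 0 where camera pointed down (adjusted p = 0.946). Pdk1 fell by 1.00 (SE 0.16) and Psat1 by 1.09 (SE 0.17). Hypoxia genes gave 2 higher, 4 lower and 16 not passed of 22, with 3 and 5 adjusted over the list alone, a median of -0.31 and camera adjusted p = 0.0202 (adjusted p = 0.335 with an estimated correlation, and 0.0974 without DMSO replicate 2). Integrated stress genes gave 2 higher, 6 lower and 11 not passed of 19, with 2 and 8 adjusted over the list alone, a median of -0.24 and camera adjusted p = 0.0134 (adjusted p = 0.313 with an estimated correlation). Fry gave 0.111 and 0.0732 for these lists.

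Genes of other cell types were also measured in these cultured cells. Cd68, a lysosomal protein of macrophages, rose from 5.76 ± 0.178 to 24.6 ± 5.32 CPM (2.10 ± 0.30), and Cd14, the lipopolysaccharide co-receptor, held 95 reads against 3 (ratio 33.4, 11.1 to 165). Of 13 macrophage genes, 5 rose, 0 fell and 8 did not pass, with 6 adjusted over the list alone, a median of 1.77 and camera adjusted p = 0.0031 (adjusted p = 0.274 with an estimated correlation). Pdgfrb rose by 4.09 ± 0.45 and Col1a1 by 3.13 ± 0.49. Of 10 matrix genes, 5 rose, 0 fell and 5 did not pass, with 6 adjusted over the list alone, a median of 1.77 and camera adjusted p = 0.0031 (adjusted p = 0.274 with an estimated correlation). Lists that did not pass camera were T-cell identity (6 higher, 1 lower of 22, 9 and 1 adjusted over the list alone, adjusted p = 0.0596, and 0.0137 without DMSO replicate 2), genes methylated in NK/T lymphoma (6 higher, 1 lower of 15, 9 and 1 over the list alone, 0.114, and 0.014 in fry) and nucleoside genes (2 higher, 2 lower of 16, 2 and 3 over the list alone, 0.166). Retrovirus-silencing genes (2 higher, 2 lower of 20, the same over the list alone, 0.199), B-cell genes (0 of 8, 0.289, and 0.00855 without DMSO replicate 2), endothelial genes (2 higher of 7, 0.536) and cytotoxic genes (0 of 6, 0.977) did not pass either. Too few for a test were neutrophil (3 higher of 3), dendritic (1 higher and 1 lower of 4) and keratinocyte (1 higher of 4) genes. Skeletal muscle genes had 0 of 3 past the threshold with either drug and 3 of 3 higher adjusted over the list alone.

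Other genes of the naming rule passed with decitabine but lost their calls without a library. Cox6a2 (-3.28 ± 0.74), Or6b13 (-2.83 ± 0.63) and the growth regulator gene Mxi1 (0.71 ± 0.17) did so without decitabine replicate 1 (0.0597, 0.0741, 0.0585), decitabine replicate 2 (0.0848, 0.0503, 0.105) or DMSO replicate 2 (0.0874, 0.0569, 0.115). H2-Oa (1.68 ± 0.40) and the glycolytic gene Pgk1 (-0.75 ± 0.18) did so without decitabine replicate 1 (0.0898, 0.0649), decitabine replicate 2 (0.0525, 0.136) or DMSO replicate 1 (0.0883, 0.0623). The cytokine gene Tnf (1.05 ± 0.26) and the retrotransposon-derived Rtl8b (1.08 ± 0.31) did so without decitabine replicate 2, DMSO replicate 1 or DMSO replicate 2. The interleukin-2 receptor gene Il2ra (2.11 ± 0.53) needed decitabine replicate 1 (0.254) and DMSO replicates 1 (0.0576) and 2 (0.054), Scart1 (-2.40 ± 0.64) decitabine replicate 1 (0.14) and DMSO replicate 2 (0.187), and lymphotoxin alpha Lta (1.86 ± 0.42) decitabine replicates 1 (0.0709) and 2 (0.0597). Sesn2 (1.08 ± 0.22) needed decitabine replicate 2 (0.0735), Rtl5 (41 reads against 1, ratio 43.2, 7.33 to 1750) decitabine replicate 2 (0.103) and DMSO replicate 1 (0.0528), and Adgre1 (112 against 1, ratio 118, 20.8 to 4700) decitabine replicate 1 (0.0718). Cox6a2 (0.0797), Scart1 (0.0557) and Adgre1 (0.0563) were also lost in voom, Rtl8b with the replicate block (0.0581), and Rtl8b (0.0605) and Scart1 (0.0544) in a fit of the 4 libraries alone.

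Azacytidine and decitabine called 2614 genes in the same direction, 1960 higher and 654 lower, and 1 gene in opposite directions. Among genes called by both, 1606 of 2615 had the larger absolute log2 fold change with azacytidine, with a median difference of 0.088. Without decitabine replicate 1 the larger change was with azacytidine in 955 of 2126. Azacytidine alone called 1266 genes and decitabine alone 583, an order that turned around without azacytidine replicate 1 (228 and 1083) or 2 (584 and 873). Without decitabine replicate 1 or 2 the counts were 1671 and 204 or 2401 and 188. Independent lists of these sizes would share 378. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.946. Both comparisons use the same DMSO libraries, which alone gave r = 0.496 (0.477 to 0.511) and 0.85 shared calls (0 to 5) in 20 simulated draws with no drug effect. The observed covariance was 2.48 against 0.114 in those draws. Shared calls numbered 1447 without azacytidine replicate 1, 1642 without azacytidine replicate 2, 1331 without decitabine replicate 2 and 1709 without DMSO replicate 1.

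**Figure D3:**
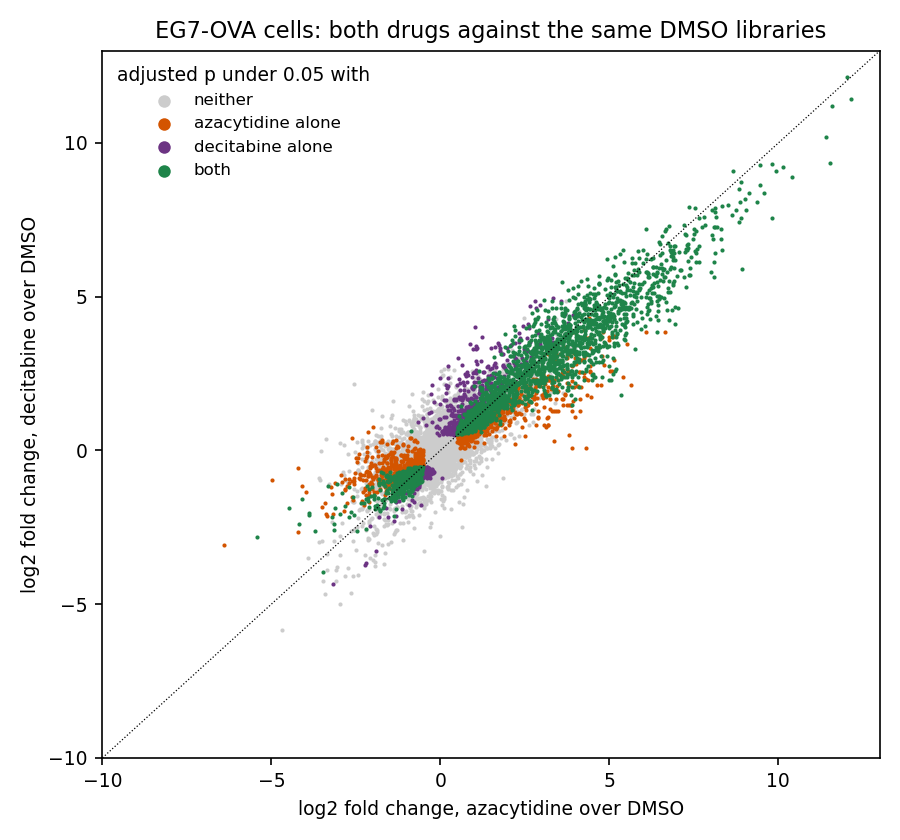
Log2 fold change of each EG7 gene with decitabine against that with azacytidine, each over DMSO, coloured by which drug passed an edgeR adjusted p of 0.05, with genes at 0 reads in a group drawn at their bound and a dotted line where both are equal. Both drugs called 2614 genes in the same direction and 1 in opposite directions.

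The direct contrast of the drugs compared related compounds at different doses, 1.5 µM and 0.2 µM. No gene passed in the main edgeR fit, though some did in DESeq2 and in edgeR with no filter on low counts. List calls were lost with an estimated correlation and in fry (germline and class II 0.549 and 0.43). Among germline genes, azacytidine minus decitabine, Dazl differed by 1.44 ± 0.27 (95% interval 0.83 to 2.05), Taf7l by 2.23 ± 0.46 (1.20 to 3.26) and Tuba3b by 1.52 ± 0.32 (0.81 to 2.22). Peg10 had the smallest adjusted p (0.0946) with a difference of 3.04 ± 0.37 (2.19 to 3.88), and Cdkn1c differed by 1.97 ± 0.42 (1.03 to 2.90). Among class II genes, H2-Eb1 differed by -1.20 ± 0.23 (-1.70 to -0.69) and Cd74 by -0.99 ± 0.23 (-1.51 to -0.48). The receptor gene Cd28 differed by -0.88 ± 0.17 (-1.25 to -0.50). Intervals included 0 for Cd274 (0.06 ± 0.31, -0.63 to 0.75), Isg15 (0.19 ± 0.46, -0.83 to 1.22), Rigi (-0.25 ± 0.18, -0.66 to 0.16), B2m (-0.08 ± 0.17, -0.45 to 0.28) and Dnmt3a (0.14 ± 0.19, -0.27 to 0.55). Those of Dnmt1 (0.44 ± 0.16, 0.079 to 0.79) and Zbp1 (-0.75 ± 0.28, -1.36 to -0.13) excluded 0 before adjustment. EdgeR called 0 of 19123 genes, with 1219 at an unadjusted p under 0.05, while voom called 0 and DESeq2 177, of which 39 were higher and 138 lower. EdgeR called 5 genes without decitabine replicate 2. Groups did not overlap for 35% of genes, where chance gives 33.3%, and the median interval reached 0.743 to either side of the estimate.

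As lists, camera placed germline genes higher with azacytidine than with decitabine (31 tested, median 1.29, camera adjusted p = 1.67e-13), and so were imprinted genes (median 0.13, camera adjusted p = 0.0209; 0.0915 without azacytidine replicate 1). Both had adjusted p = 0.549 with an estimated correlation and 0.43 in fry, and adjusted over the list alone 13 and 5 members were higher. Chemokine and cytokine genes (median -0.42) and checkpoint genes (median -0.32) were lower, each at camera adjusted p = 0.00511 and adjusted p = 0.475 with an estimated correlation, with 2 and 3 members lower adjusted over the list alone. Without azacytidine replicate 2 they were at 0.139 and 0.156. Class II genes (median -0.38, camera adjusted p = 0.0358; adjusted p = 0.549 with an estimated correlation) had 3 members lower adjusted over the list alone. Hypoxia genes (median -0.21, camera adjusted p = 0.0209) and interferon genes (median -0.075, camera adjusted p = 0.0416) had 0, and macrophage genes (median -0.86, camera adjusted p = 0.0416) had 1. These 3 lists had adjusted p = 0.603 with an estimated correlation. Class II, hypoxia and interferon calls were lost without azacytidine replicate 2 (0.161, 0.548, 0.341) or decitabine replicate 2 (0.24, 0.101, 0.248). The macrophage call was lost without azacytidine replicate 1 (0.0657) or 2 (0.156) or decitabine replicate 1 (0.209). Fry called 0 lists. Over all genes 0 members of these lists passed in the main edgeR fit. The other 17 lists had camera adjusted p from 0.122 to 0.997. Of these, cell-cycle (0.00129), matrix (0.0125) and p53 genes (0.00577) passed without decitabine replicate 1 and T-cell identity (0.0128) without azacytidine replicate 1. Retrovirus-derived genes passed without azacytidine replicate 2 (0.0155) or decitabine replicate 2 (0.0479).

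In NKYS cells azacytidine raised Dazl, as in EG7 cells, from no read to 14.6 ± 4.16 CPM, at least 17.4-fold. Wnt11, a secreted signalling protein, was at least 37.8-fold higher, the GTPase-activating protein gene Arhgap5 at least 31.6-fold, the transcription factor gene Mecom at least 28.9-fold and Rhob, a small GTPase gene, at least 27.4-fold. Hoxd10, Rab13 and Prrx1 were at least 20.1-fold, 21.6-fold and 20.4-fold higher. Rbpms, an RNA-binding protein gene, fell from 125 ± 0.805 to 19.2 ± 1.09 CPM (-2.70 ± 0.16) and the transcription factor gene Tfap2b from 210 ± 0.299 to 52.6 ± 1.94 CPM (-2.00 ± 0.11). Arl4c (-1.90 ± 0.15), Hecw2 (-1.88 ± 0.16) and Tmem65 (-1.77 ± 0.23) fell as well. The comparison asks whether a human NK/T lymphoma line answers the drug. Every gene identifier of this table was a mouse Ensembl gene although the labels call the cells human, so these values describe reads assigned to mouse gene models and are uncertain for every gene.

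Of 2672 genes tested in NKYS, 160 passed, 91 higher and 69 lower, and 51 of them had an absolute log2 fold change above 1. The groups did not overlap for 53.4% of genes, where chance gives 33.3%. Counts were 26 without DMSO replicate 1, 24 without DMSO replicate 2 and 326 without azacytidine replicate 2. Without DMSO replicate 1 and 2 the adjusted p of Dazl were 0.0795 and 0.0809 and those of Prrx1 0.0643 and 0.0682, and without DMSO replicate 2 that of Rab13 was 0.052. Adgrb3 (-2.88 ± 0.50), Dennd1a (-1.45 ± 0.28) and Magi2 (-2.08 ± 0.30) passed but lost their calls without DMSO replicate 1 (0.128 and 0.147 for the first pair) or 2 (0.152, 0.13 and 0.0951), and Dennd1a in DESeq2 (0.0689). The 7SK and 7SL small RNAs took 38.0% to 47.7% of counts. Psme2, of the class I list, rose by 6.07 ± 0.56, though its reads can be shared with a near-identical copy, while Canx (0.36 ± 0.31) and Pdia3 (0.34 ± 0.31) did not pass. Taf9b (0.36 ± 0.17), Top2a (0.03 ± 0.08), Mcm4 (0.01 ± 0.09), Ccne2 (0.31 ± 0.27) and Dnmt3a (0.96 ± 0.53) did not pass. Camera tested 2 lists, DNA methylation (0 of 8 genes past the threshold, median 0.12) and retrovirus silencing (0 of 7, median -0.11), each at adjusted p = 0.706, and fry gave 0.524 and 0.293. Of 40 interferon genes 0 had 10 reads over the libraries, as did 0 of 28 checkpoint genes, 4 of 23 class I genes and 1 of 23 RNA-sensing genes. Gapdh, Cd274, Cd2, Cd3e, Gzmb and Prf1 had 0 reads over the 4 libraries, which allows up to 0.813 CPM, so no response of these genes was detectable.

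**Figure D4:**
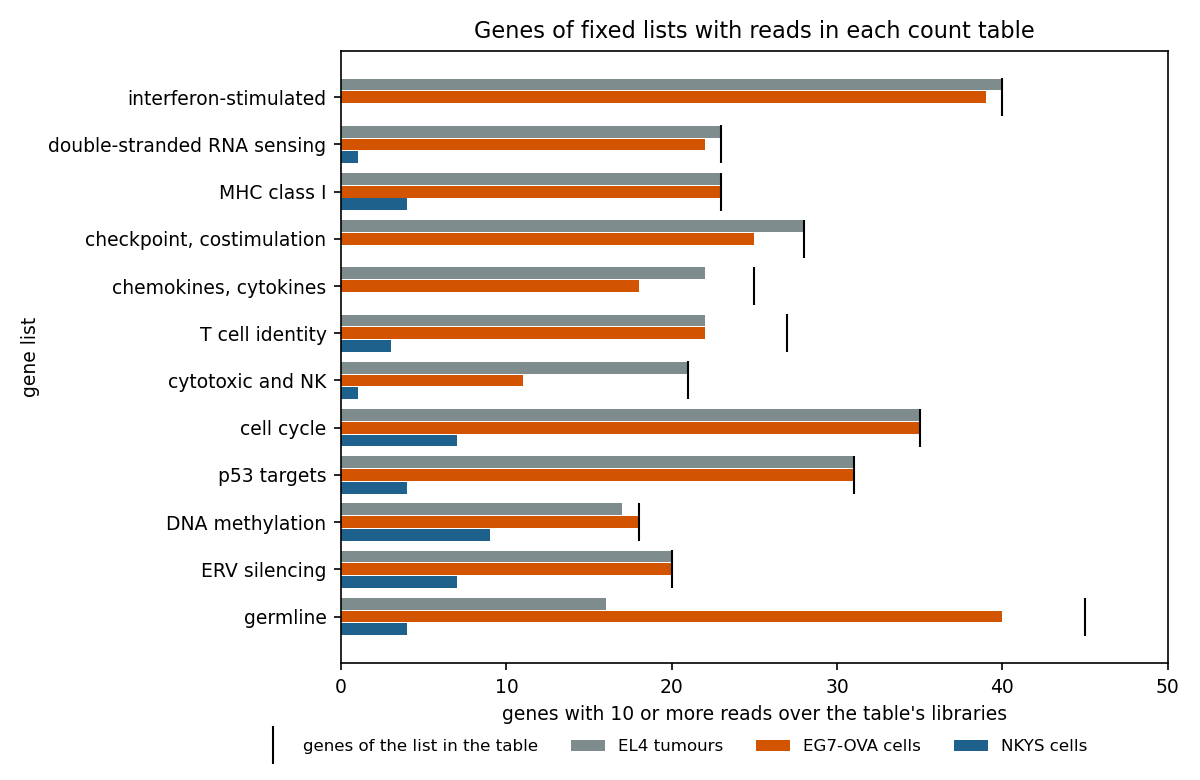
Bars give the number of genes of each fixed list with at least 10 reads over the libraries of the EL4, EG7 and NKYS tables, and ticks the number of genes of the list in the table. For the interferon list the bars stand at 40, 39 and 0 of 40 genes.

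Among 2349 genes tested in both EG7 and NKYS, 18 were higher with azacytidine in both lines where 7.24 would be shared by chance (odds ratio 3.16, one-sided Fisher's exact test, adjusted p = 0.00035). Rhob (5.71 in EG7, 8.26 in NKYS), Dazl (8.31, 7.60), Marcks (5.47, 6.65) and Socs3 (7.13, 0.79) were among them, with Marcks and Socs3 chosen after their values were seen. In the lower direction 11 genes were shared, against 5 by chance (odds ratio 2.64, adjusted p = 0.00907), including Hecw2 (-1.54, -1.88) and the transferrin receptor gene Tfrc (-0.75, -0.53), which was chosen after its values were seen. Both overlaps rested on each NKYS DMSO library. Without DMSO replicate 1 and 2 of NKYS, 1 and 2 genes were shared in the higher direction and 1 and 1 in the lower. Without EG7 azacytidine replicate 1 and 2 the lower overlap was 2 and 3. Of 36 genes called in both lines, 7 moved in opposite directions.

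Genes lower in P3 overlapped with genes raised by the drugs in EG7, but same-direction overlap was not tested. Over 14166 genes, 532 were lower in P3 and raised by azacytidine against 388 by chance (odds ratio 1.64, one-sided Fisher's exact test, adjusted p = 1.58e-17). With decitabine 510 were shared against 353 (odds ratio 1.77, adjusted p = 1.57e-21). Genes higher in P3 and lowered by a drug numbered 150 against 193 and 72 against 130, with adjusted p = 1 for both. Leaving out marker lists of other cell types (14101 genes left) gave 525 and 501, too small a removal to exclude other cells. Within the interferon, class I and macrophage lists the overlap lay near chance, given the numbers lower and raised. This cannot test whether a list as a whole moved in opposite directions. Of 37 interferon genes, 15 were lower in P3 and raised by azacytidine, among them Irf1, Gbp2, Igtp and Irgm1, against 15.5 by chance, and 15 with decitabine against 16.2. Of 23 class I genes, 5 did so with either drug, H2-T22 and H2-T23 among them, against 4.17. Of 22 checkpoint genes, 3 were lower in P3 and raised by azacytidine and 3 by decitabine, Cd80 with both, against 3 and 4.5, while 1 and 4 were higher in P3 and raised. RNA-sensing genes gave 4 lower and 4 higher in P3 among those raised by each drug, and germline genes 0 lower and 5 higher. Of 13 macrophage markers, 4 that were lower in P3 rose with each drug in cultured EG7 cells, Cd68 and Lyz2 among them, against 3.85. All of these overlaps were 0 without either P0 library, since edgeR then called no gene in the tumours.

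**Figure D5:**
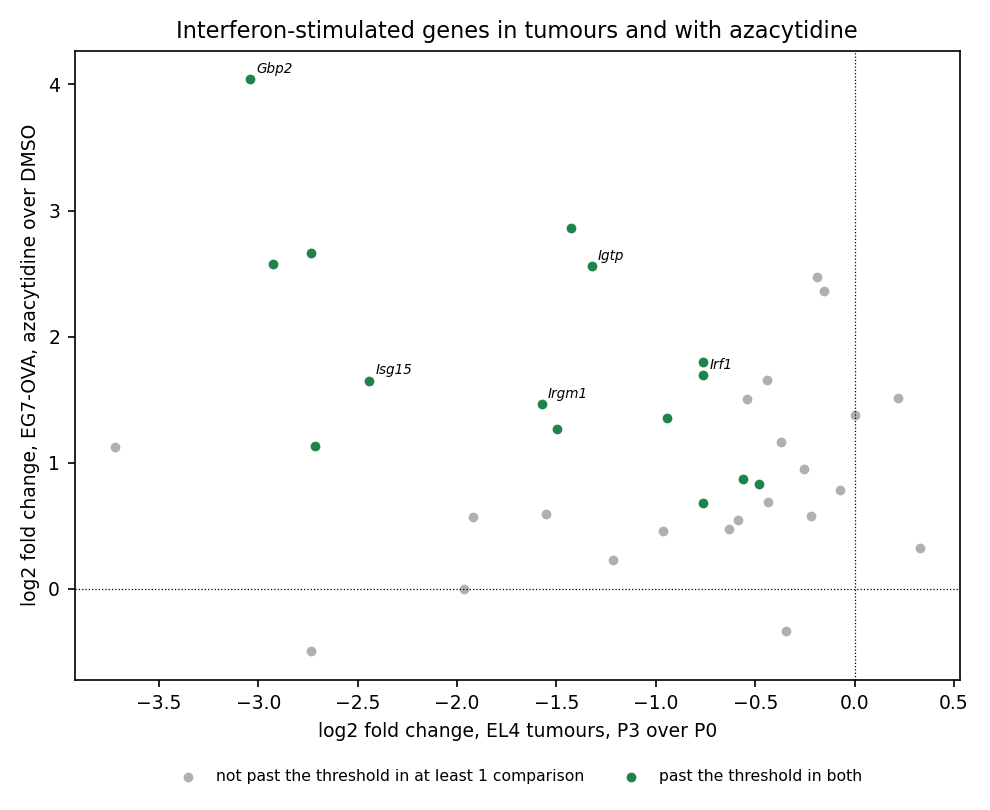
Log2 fold change of 37 interferon-stimulated genes in P3 against P0 EL4 tumours on the horizontal axis and with azacytidine against DMSO in EG7 cells on the vertical axis, with 15 genes past an edgeR adjusted p of 0.05 in both drawn in green. The green genes lie below 0 in the tumours and above 0 with azacytidine. With 25 of the 37 lower in P3 and 23 raised, chance would give 15.5.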

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

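The tests for mouse cells and for neutrophil and endothelial against macrophage markers were chosen only after the result was seen, and so were the spreads used to read the mouse-cell, interferon and X-chromosome tests.

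The NKYS libraries held a read in 5033 to 5513 genes other than 7SK and 7SL. EG7 libraries thinned to the same number of reads held 15746 to 18076, at least 2.84 times as many, which argues against too few reads. Of the 100 coding genes most abundant in EG7 and EL4, 10 had no read (binomial interval over genes 4.9 to 17.6), against 0 (up to 3.62) in EG7 and EL4 libraries thinned alike, which argues against mouse cells as the only source, while the 40 that reached 10% of their EG7 level (30.3 to 50.3) do not decide against a bound of 50. Long non-coding genes made up at most 0.873% of the genes of known class with a read, against 10.6% to 11.7% in thinned EG7 libraries and 13.4% and 18.5% of the NKYS and EG7 table entries of known class, as counting human reads against mouse gene models would give. No biological explanation was tested, and a share of mouse reads stays open.

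Macrophage, B-cell and dendritic markers were lower in P3 tumours. A smaller share of every other cell type would lower all markers alike. The neutrophil median lay 4.49 above the macrophage median. Over single libraries the log2 ratio of their marker sums lay at least 2.85 higher in P3, against a range of up to 1.9 within a group. For endothelial to macrophage sums these were 1.37 and 0.323. Over 2 libraries per group this argues against an even loss. A changed mix of other cells or a fall in the lymphoma cells stays open. Of 7 interferon genes that cultured EG7 cells hold at 50% or more of the P0 level, 2 (Isg20 and Cmpk2) fell by more than 1 on the log2 scale. This met the bound set beforehand by less than its binomial spread over genes, and medians were -0.59 for the 7 and -0.95 for the others, so loss of other cells alone and a fall within the lymphoma cells cannot be told apart. What the P0 and P3 labels name was not tested apart from cell composition.

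Xist rose with both drugs in EG7 cells, from 0.275 CPM to 861 and 669 CPM. If it silenced the X chromosome, X-linked genes would fall against autosomal genes. Over 305 X-linked and 9923 autosomal genes at 5 CPM or more, Xist left out, the median difference was -0.042 with azacytidine (value -0.0419, bootstrap interval over genes -0.14 to 0.056, one-sided permutation p = 0.144) and 0.017 with decitabine (-0.063 to 0.108, one-sided permutation p = 0.679). Of all 529 X-linked genes tested, at any level, 121 were raised and 37 lowered with azacytidine (22.9% raised, against 13.5% of autosomal genes, odds ratio 1.90, Fisher's exact test, adjusted p = 1.44e-08) and 108 raised and 18 lowered with decitabine (20.4% against 12.4%, odds ratio 1.81, adjusted p = 2.33e-07). Silencing of part of the chromosome beside drug-induced rises elsewhere on it cannot be told apart from no silencing, since the median pools both.

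These 7 genes passed in EG7 and NKYS with azacytidine in opposite directions in each library, and the difference was not tested. The difference of the log2 fold changes, EG7 minus NKYS, was -1.46 for Aida (-0.74 and 0.71), 1.52 for Cited2 (1.11 and -0.41), -3.84 for Hoxb9 (-1.34 and 2.51) and 3.58 for Samd4 (2.53 and -1.05). It was 4.59 for Sulf1 (3.17 and -1.42), -4.25 for Thrb (-1.19 and 3.06) and 7.62 for Zswim6 (6.85 and -0.77).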

How the results depend on the processing

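The count at 1 CPM or more in EG7, DESeq2 without each P0 library and NKYS without 7SK and 7SL were chosen only after the result was seen. Beside the 7736 genes of the tumours, 4239 had an absolute log2 fold change above 1 and 4680 were at 1 CPM or more in EG7. Leaving out each library gave 0 to 11286 in edgeR, with 0 without EL4_P0 replicate 1 or 2, where 5571 and 5768 passed an unadjusted p of 0.05, voom called 0 and DESeq2 called 2267 and 2201. Camera with an estimated correlation called 0 lists in the tumours, with azacytidine, with decitabine and between the drugs, where fry also called 0. Leave-one-out counts were 1675 to 3895 with azacytidine, 1520 to 3288 with decitabine, 0 to 5 genes and 3 to 10 lists between the drugs, 24 to 326 in NKYS and 1331 to 2749 for the response shared by both drugs. Between the drugs DESeq2 called 177 genes and the fit with no filter 378, against 0 in edgeR and voom with 1219 at an unadjusted p under 0.05. In NKYS no filter gave 333, an absolute log2 fold change above 1 gave 51 and leaving out 7SK and 7SL gave 167. The response shared by EG7 and NKYS ranged from 1 to 25 genes higher and 1 to 24 lower when each library was left out, and 1 gene was lower in both with an absolute log2 fold change above 1. Genes lower in P3 and raised by azacytidine ranged from 0 to 770 and by decitabine from 0 to 746, or 0 to 761 and 0 to 734 without the marker lists of other cell types. Genes higher in P3 and lowered ranged from 0 to 232 and 0 to 141. Over all alternatives, 2676 of 2940 results for named genes were the same, 228 weaker and 36 stronger, and for lists 728 of 848 were the same, 93 weaker and 27 stronger, with 0 reversed in either. Deviations of replicate 1 from its group's mean correlated between groups at r = -0.037 in EL4, -0.257 to 0.273 in EG7 and -0.088 in NKYS, which bears on the replicate block. In EG7 the titles of the DMSO samples number them 2 and 3, so the pairing and the block values are uncertain there. The pseudocount alternative was not run, since the tables hold counts. The cause of these shifts was not tested.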

Other observations

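The genes in this part were chosen only after the result was seen, and their tests are those of the comparisons above. An imprinted neighbourhood on chromosome 6 moved in part in the tumours. Sgce (4674350 to 4747207, mm10) was 6.15 ± 0.14 higher in P3 and Ppp1r9a (4902917 to 5165661) 7.58 ± 0.25, while Casd1 (4600839 to 4643355) rose from 63.9 to 95.8 CPM (0.58 ± 0.11). Peg10 (4747306 to 4760517), which lies between Sgce and Ppp1r9a, stayed at 0.397 and 0.543 CPM (-0.44 ± 0.56, edgeR adjusted p = 0.556). In EG7 cells Peg10 was at least 482-fold higher with azacytidine and 59.7-fold with decitabine. The tumour calls ended in edgeR without P0 replicate 1 or 2, where 0 genes were called.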
